A study of Mus musculus with 2 samples.

How the data were processed

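Small RNA libraries were made from the gastrocnemius, the large calf muscle, of 2 female mice aged 36 days. The mice were B6CASTF1/J, first-generation hybrids of C57BL/6 and CAST/EiJ parents. The labels number them as biological replicates 1 and 2 and describe them as separate females, so each library was taken as 1 animal and the design holds 1 group. Both records also carry the same donor identifier. If that stands for 1 mouse, every SD and every difference between the animals measures technical spread only. Per the labels, total RNA was used and the library size range was under 30 nucleotides.

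The deposited tables hold raw counts of reads per microRNA gene for the mm10 genome build and the M21 gene annotation, per the read-me text deposited with them. The aligner and the counting program are not given in the sources used here. Each table has 4 summary rows and 3 count columns without a header. From this layout and from the values, the columns were read as counts without regard to strand, counts on the strand of the gene, and counts on the opposite strand. The counts on the strand of the gene were used. Rows are hairpin genes, so the arms of a hairpin are not told apart. Reads that match several places in the genome stand in a summary row of their own and belong to no gene. MicroRNAs with identical copies elsewhere in the genome are therefore uncertain in level, and so are levels of different microRNAs set side by side, since adapters join to different sequences with different efficiency. All 2202 gene identifiers were found in the GENCODE M21 annotation, from which symbols, positions and host genes were taken.

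The summary rows stayed out of library sizes and tests. Of 9538917 reads in replicate 1, 75.4% matched several places, 6.37% were unmapped and 1.49% lay outside microRNA genes. Of 14072830 reads in replicate 2, the corresponding shares were 77.6%, 5.98% and 1.65%. Counts per 1000000 reads (CPM) and percentages were computed over gene-assigned reads. A gene was called detected with at least 10 reads in both libraries. A count of 0 allows up to 3 counts, which is 1.88 CPM in replicate 1 and 1.44 CPM in replicate 2. Reads are not independent molecules, since PCR copies cannot be recognised, and all intervals and limits cover counting error only.

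Libraries were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3). A two-sided exact binomial test asked for each detected gene whether its reads divided between the libraries as their scaled sizes would give, with Benjamini-Hochberg adjustment at 0.05. It compares 2 libraries and not conditions, and it takes no account of the spread between animals. Folds have exact 95% intervals of the same kind. The usual spread was described by the square root of edgeR's common dispersion with an intercept-only design. As an alternative, edgeR's exact test was run at that dispersion, with the 2 libraries set against each other. The dispersion comes from these same libraries and holds their difference, so this alternative describes which ratios are large for their depth and is no test against a spread between animals. The homogeneity of the libraries was tested with a chi-square test over detected genes. No comparison of groups could be made.

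Before the data were examined, 25 lists with 248 entries (muscle, other cell types, families and clusters) and 30 pairs of neighbouring genes were fixed, and 246 entries were matched to a gene. For each list the share of reads was computed. Its median log2(CPM + 1) was ranked among 10000 random lists of the same size. Its median log2 ratio between the animals was set against 10000 random lists drawn for each member from the 21 detected genes nearest in mean expression. These ranks describe the 2 libraries and are not tests. The genes named were the 20 most abundant, up to 4 of the most abundant members of each list, both members of detected pairs, and the 5 highest and 5 lowest ratios among genes with a mean of at least 100 reads that passed the binomial test. Genes given values beyond that rule are said to be so.

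The procedures were tested on counts simulated for these 2 libraries. With no gene changed, 0% of 283 genes were called and the chi-square was 1.08 per degree of freedom. With 200 genes changed, of which some stayed under the detection minimum, 72.9% of 48 tested genes changed 1.5-fold and 100% of 41 changed 3-fold were recovered. In that simulation 1.04% of the unchanged genes among 281 tested were called. Both of these simulations held counting noise only and no spread between animals, so their call rates do not carry over to the calls in the real libraries. A coefficient of variation of 0.3 was estimated as 0.274 over 274 genes. Alternatives were counts without regard to strand, other scalings and read minimums, other pseudocounts, leaving out the most abundant gene, leaving out each replicate, and the common dispersion. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with DESeq2 1.42.0 for the alternative size factors.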

Results

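MicroRNA gene counts were obtained for the gastrocnemius of 2 female B6CASTF1/J mice aged 36 days, with 1 library per animal and no other group. Replicate 1 had 1593787 reads assigned to microRNA genes and replicate 2 had 2078101. Of 2202 annotated microRNA genes, 561 had a read in either library and 273 (12.4%) had at least 10 reads in both. These 273 genes held 99.95% and 99.9% of the reads.

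The ranks given here leave out reads that match several places, 75.4% of all reads in replicate 1 and 77.6% in replicate 2. Genes with identical copies may therefore rank too low. Mir378a, which lies in an intron of Ppargc1b (a coactivator gene of mitochondrial metabolism), was the most abundant gene, with 15.9% ± 2.10 of gene-assigned reads (SD, n = 2). With multiply matched reads added to the total only, a measure chosen afterwards, its counted reads were 2.73%. Any multiply matched reads of its own are not in that share. Among gene-assigned reads the endothelial Mir126a in Egfl7 came next with 10.04% ± 1.72. Mir143, a microRNA of smooth muscle and other mesenchymal cells, followed with 8.95% ± 4.03. The order differed by animal, as Mir143 held 11.8% in replicate 1, above the 8.82% of Mir126a, and 6.10% in replicate 2, below Mirlet7g with 7.50% and Mir206 with 6.70%. Mirlet7g held 6.63% ± 1.24, Mirlet7i 5.28% ± 0.109 and the skeletal muscle gene Mir206 4.38% ± 3.28. Mir23a, Mir23b, Mir99a and Mir22 held between 2.69% and 4.24% each. The 10 most abundant genes of a library took 65.7% ± 0.548 of its reads, and 8 genes were among the top 10 of both animals. Mirlet7d, Mir30a, Mir451a, Mir127, Mir10b, Mir26b, Mir411, Mirlet7b, Mir30d and Mir322 completed the 20 highest means. Mir378a is at chromosome 18, 61397835 to 61397900, with the annotated gene Gm25301 on the other strand. It had 0 reads when strand was disregarded, because reads in genes that overlap on opposite strands are then left as ambiguous. Mir451a then also had 0 reads and Mir126a nearly none.

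**Figure D1:**
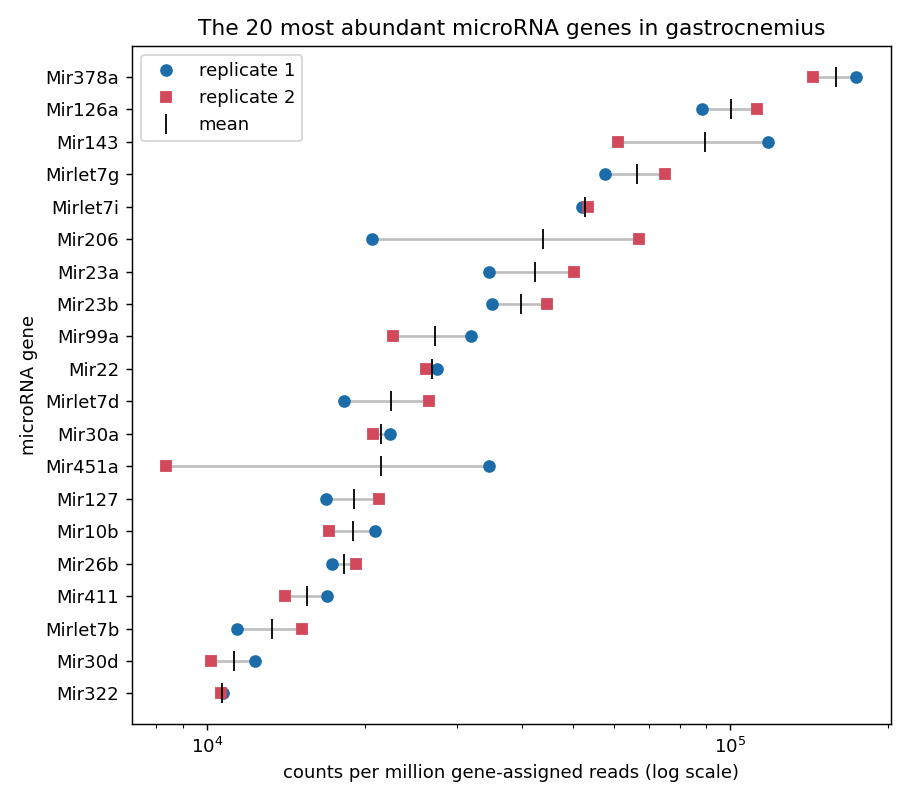
CPM over gene-assigned reads (log axis) of the 20 most abundant microRNA genes, with a circle for replicate 1, a square for replicate 2 and a bar for their mean. Mir206 and Mir451a lie farthest apart between the animals, with 3.40-fold more Mir206 and 0.253 times the Mir451a in replicate 2 after scaling.

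Among the muscle microRNAs, all 11 listed members had reads and 8 were detected, together holding 2.21% of reads in replicate 1 and 6.98% in replicate 2. Mir206 made up most of them, with 32871 and 139295 reads. Mir486 had 1549 and 2431 reads and Mir1a-2 had 587 and 835. Mir133a-1 had 47 and 43 reads and Mir133b had 26 and 34. Mir1a-1 and Mir1a-2, like Mir133a-1 and Mir133a-2, give the same mature microRNA, and reads that match several places are in no gene's count. The levels of these genes are therefore uncertain. So is that of Mir133b, whose hairpin shares a 20-base stretch with another microRNA locus. The 52 measured genes of the list of such identical copies held 1.20% and 1.35% of gene-assigned reads, and 34 of them were detected. Reads matching several places were 4.51 times as many as gene-assigned reads in replicate 1 and 5.25 times in replicate 2.

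The list of microRNAs of muscle differentiation held 17.9% ± 2.19 of reads (n = 2), with 15 of 17 members detected, and Mir378a, Mir322, Mir27b and Mir29a were its highest members. Mir378a alone held 15.9% of reads, and without it the list held 2.38% of the remaining reads. Large families were well represented. The let-7 list held 16.7% ± 2.38 with 13 of 14 members detected, led by Mirlet7g, Mirlet7i, Mirlet7d and Mirlet7b. The miR-10 family, with Mir99a, Mir10b, Mir100 and Mir10a highest, held 6.56% ± 0.827. The imprinted Dlk1-Dio3 cluster on chromosome 12 held 5.99% ± 0.294, with 42 of 47 members detected and Mir127, Mir411, Mir379 and Mir434 highest. The miR-30 list held 4.09% ± 0.287, and the miR-17-92 list, with Mir17, Mir93, Mir20a and Mir106b highest, held 0.652% ± 0.177.

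Marker lists of other cell types varied widely in level. The endothelial list held 10.1% ± 1.72 of reads (0.0526% without regard to strand), nearly all from Mir126a, while Mir221 had 565 and 698 reads. The smooth muscle list held 9.14% ± 4.08 from Mir143 and Mir145a. The erythroid list of Mir451a and Mir144 held 2.32% ± 2.01 (0.247% without regard to strand). Leukocyte markers held 0.176% ± 0.0473 and glial markers 0.103% ± 0.0693 (mostly Mir338, and 0% without regard to strand). Fibroblast markers held 0.0675% ± 0.00324 and neural markers 0.0544% ± 0.0211. Of the neural list, Mir128-1 and Mir128-2 were detected and 5 of 10 members had no read in either library. All Mir9, Mir124a and Mir128 genes of that list have identical copies, as do Mir199a-1 and Mir199a-2 of the fibroblast list. The hairpin of Mir199b shares a 20-base stretch with another microRNA locus. Reads that match several places are in no gene's count, so low or missing counts of these genes do not show absence. Epithelial markers held 0.0216% ± 0.00911, the liver marker Mir122 0.0184% ± 0.00243 and the sensory list of Mir182, Mir183 and Mir96 0.00803% ± 0.00932. The pancreas list held 0.00523% ± 0.00553, the gut and kidney list 0.00498% ± 0.000572 and the hypoxia gene Mir210 0.00444% ± 0.00179. The inflammation list, led by Mir21a, held 0.883% ± 0.124. The heart gene Mir208a, in an intron of Myh6, had 1 and 15 reads. None of the 14 pluripotency genes was detected, and 11 had no read in either library. For reads placed at 1 locus this allows up to 1.88 CPM each in replicate 1 and 1.44 CPM in replicate 2. It sets no limit on reads that match several places, and 2 genes of the miR-302 family share a 20-base stretch with another microRNA locus.

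Differences of over 2-fold between the animals included microRNAs from slow-fibre myosin genes, Mir206, the erythroid microRNAs, Mir375 and Mir182. Mir499, in an intron of Myh7b, was 14.3-fold higher in replicate 2 (95% counting interval 11.5 to 17.9, 86 against 1527 reads). Mir206 was 3.40-fold higher (3.36 to 3.45). Mir208b, in an intron of the slow myosin gene Myh7, had 5 reads in replicate 1 and 889 in replicate 2, a ratio of 143 with an interval of 61.0 to 441, and was below the minimum for testing. Mir451a was 3.95-fold lower in replicate 2 (3.88 to 4.02) and its neighbour Mir144 was 4.25-fold lower (4.00 to 4.53).

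The counts of the libraries over the 273 detected genes differed beyond counting noise, with a chi-square of 572 per degree of freedom (272 degrees of freedom), which was 280 with no filter and 778 with at least 50 reads in both. Across genes, which are not independent replicates, log2(CPM + 1) had a Pearson's r of 0.973 and a Spearman's rho of 0.962. The exact binomial test called 172 genes, 91 higher and 81 lower in replicate 2. The balance turned to 78 higher and 92 lower with scaling by total reads, and to 81 higher and 99 lower with no filter. More than 2-fold differences were found for 33 genes. The median absolute log2 ratio was 0.36 and the coefficient of variation between the animals was 0.335. Each animal gave 1 library, so spread between animals and spread between library preparations cannot be told apart. With edgeR's exact test at the common dispersion, which was estimated from these same 2 libraries, 4 genes passed in place of 172, or 1 with at least 50 reads in both and 5 with no filter. The 4 were Mir499, Mir375 and Gm26117, all higher in replicate 2, and Mir182, which was lower. Mir206 (adjusted p = 0.365), Mir451a (0.230) and Mir144 (0.212) did not pass with edgeR at that dispersion. Gm26117 was named after its value was seen.

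**Figure D2:**
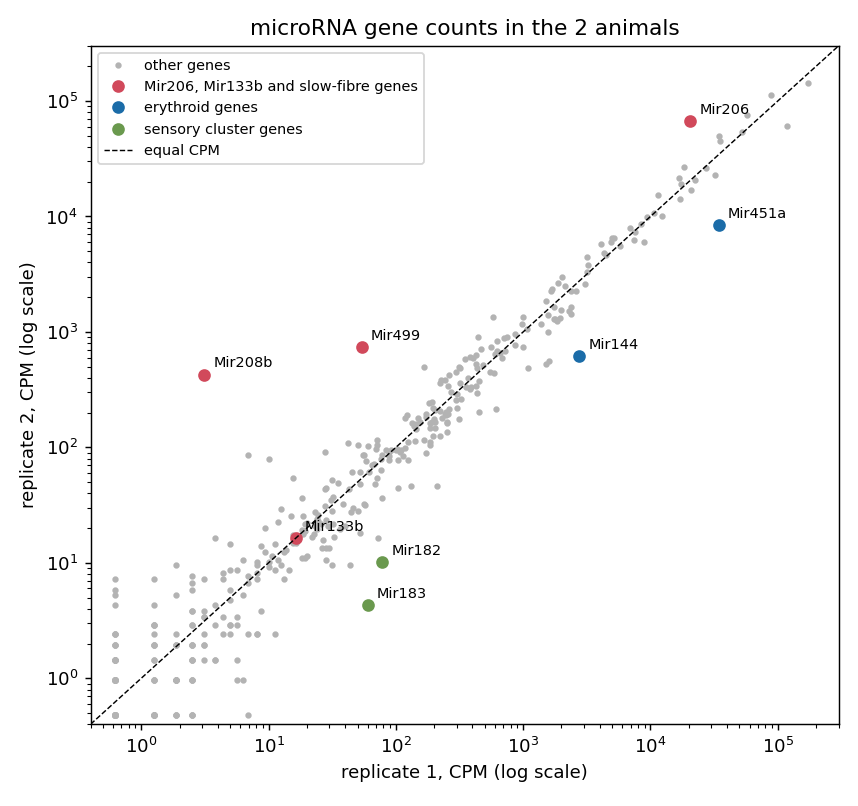
CPM in replicate 1 (horizontal, log axis) and replicate 2 (vertical, log axis) for each of the 414 microRNA genes with a read in both libraries, with the dashed line at equal values. Mir206, Mir499 and Mir208b lie above the line, Mir144, Mir451a, Mir182 and Mir183 below it, and Mir133b, with 26 and 34 reads, on it.

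Of the 8 detected muscle microRNAs, 4 were higher in replicate 2, none was lower and 4 did not pass the test. Mir486 was 1.26-fold higher (1.18 to 1.34) and Mir1a-2 1.14-fold (1.03 to 1.27), a call that ended with scaling by total reads. Mir133b, 3686 bases from Mir206 on chromosome 1, had a fold of 1.05 (0.612 to 1.82). Of the muscle differentiation list, 6 members were higher, 4 lower and 5 did not pass, while its share of reads was 19.5% in replicate 1 and 16.4% in replicate 2, mostly that of Mir378a (17.4% and 14.4%). Mir214 was 1.57-fold higher (1.43 to 1.72) and Mir181a-2 3.49-fold (2.5 to 4.96), whereas Mir29c was 2.73-fold lower (2.54 to 2.92) and Mir378a 1.15-fold lower (1.15 to 1.16). Mir1a-2, Mir486 and Mir181a-2 are in the list of identical copies. The hairpins of Mir29c and Mir378a share a 20-base stretch with another microRNA locus. The folds of these genes cover only reads placed at 1 locus and need not hold for the mature microRNA.

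Markers of other cell types moved in both directions. Both detected smooth muscle genes were lower in replicate 2, Mir143 by 1.85-fold (1.83 to 1.86) and Mir145a by 1.45-fold (1.38 to 1.52). Of 3 detected endothelial genes, Mir126a was 1.34-fold higher (1.33 to 1.35). The others, Mir221 with a fold of 0.993 (0.887 to 1.11) and Mir222 with 0.826 (0.508 to 1.34), did not pass. Of 4 detected leukocyte markers, Mir155 and Mir150 were higher, by 2.44-fold (2.27 to 2.63) and 1.65-fold (1.48 to 1.84), and Mir142 and Mir223 were lower, by 2.11-fold (1.87 to 2.38) and 2.01-fold (1.5 to 2.72). In the inflammation list 3 genes were higher and Mir21a was lower, with a median log2 ratio of 1.03, above the range of -0.39 to 0.60 that held 95% of matched random lists. The share of reads of that list went the other way, from 0.971% in replicate 1 to 0.795% in replicate 2, since Mir21a holds most of it. Its highest ratio was that of Mir146, the annotated symbol of the miR-146a gene, at 3.13-fold (2.73 to 3.60). Mir338 was 2.72-fold lower (2.53 to 2.92). Of the fibroblast list, Mir199b was 4.29-fold lower (3.41 to 5.43), Mir214 was 1.57-fold higher (1.43 to 1.72) and Mir199a-2, with a fold of 0.991, did not pass. The hairpin of Mir199b shares a 20-base stretch with another microRNA locus, and Mir199a-2 has an identical copy. Their folds cover only reads placed at 1 locus and need not hold for the mature microRNA. Mir182 was 7.41-fold lower (4.64 to 12.4). Its cluster neighbours Mir183, with 96 and 9 reads, and Mir96, with 12 and 0, were under the minimum in replicate 2. Mir128-1 and Mir128-2 of the neural list were 1.73-fold (1.56 to 1.92) and 2.75-fold (2.08 to 3.66) higher. They are identical copies, so these folds cover only reads placed at 1 locus and need not hold for the mature microRNA. Of the epithelial list, Mir203 and Mir200c were lower and Mir205 did not pass. Mir210 was 1.72-fold lower (1.24 to 2.39), and Mir122, Mir192 and Mir194-2 did not pass. Mir375 of the pancreas list was 13.1-fold higher (7.13 to 26.7) on 11 and 179 reads. Mir708 and Mir138-1, outside these marker lists, were 2.73-fold (2.44 to 3.06) and 2.74-fold (2.14 to 3.52) lower. Mir138-1 is in the list of identical copies.

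Of the 13 detected members of the let-7 family, 11 were higher in replicate 2, or 12 adjusted over the list alone, and none was lower. The binomial test called 63.0% of all genes, and no let-7 gene passed at the common dispersion. The median log2 ratio was 0.35, equal to the upper end of the range of -0.23 to 0.35 that held 95% of matched random lists. Mirlet7d was 1.52-fold higher (1.5 to 1.54) and Mirlet7g 1.37-fold (1.35 to 1.38). Counts for the other lists were the same adjusted over the list alone. In the Dlk1-Dio3 cluster 15 members were higher, 8 lower and 19 did not pass, and its median of 0.06 changed sign with scaling by total reads. Of the miR-17-92 list 2 members were higher, 5 lower and 3 did not pass, with Mir106b 2.14-fold lower (1.98 to 2.31). The miR-30 list had 2 higher and 2 lower of 6, and the miR-10 list 3 higher and 2 lower of 8.

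**Figure D3:**
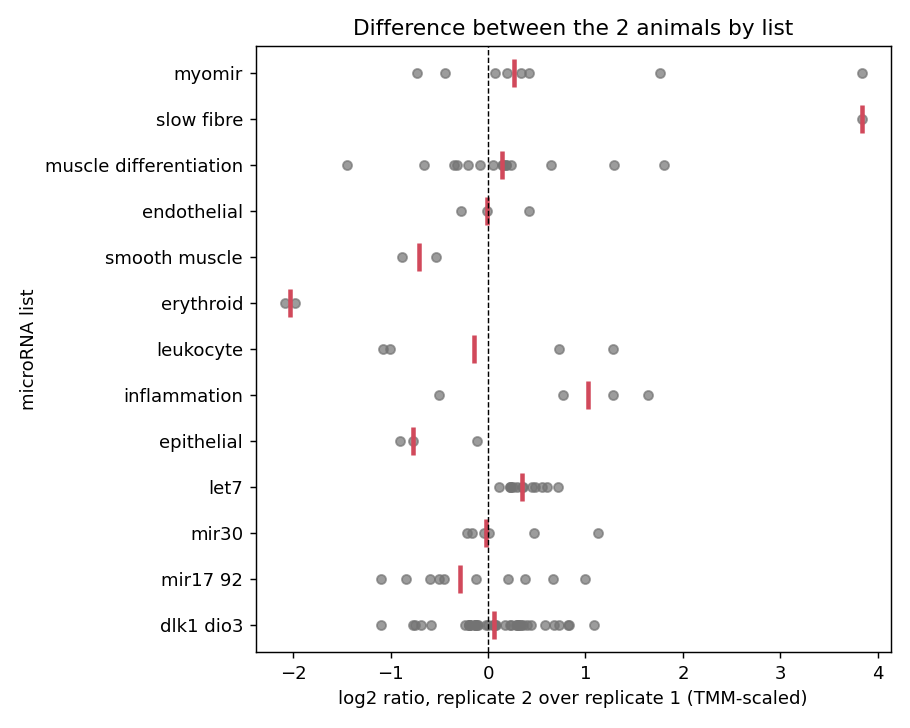
The log2 ratio of replicate 2 over replicate 1 (horizontal, TMM-scaled) for each detected member (points) of 13 of the lists, with a red bar at the list's median. The erythroid list has a median of -2.03 and the let-7 list of 0.35, and the slow-fibre list has 1 detected member, Mir499, at 3.83.

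Neighbouring genes of 1 cluster had unequal counts. Reads that match several places are uncounted and adapters join to sequences with different efficiency, so these counts do not compare the levels of the microRNAs themselves. Some pairs hold a gene with identical copies, such as Mir16-1, Mir24-1 or Mir30c-1. The hairpin of Mir133b shares a 20-base stretch with another microRNA locus. Of 29 pairs present, 24 had both genes detected. Mir206 exceeded Mir133b by 11.15 ± 1.20 on the log2 scale and Mir143 exceeded Mir145a by 5.51 ± 0.24 (SD, n = 2), while Mir15a and Mir16-1 differed by 0.01 ± 0.10. Mir451a exceeded Mir144 in both animals, with log2 ratios of Mir144 over Mir451a of -3.65 and -3.75. In 20 of the 24 pairs both genes had the same sign of difference between the animals, and in 16 with scaling by total reads. The ratio within a pair differed between the animals by a median of 0.36 on the log2 scale. Counts on the opposite strand made up 24.2% and 22.4% of the counts on both strands. Nearly all of them, 508697 and 600542, were at the 64 genes that have a microRNA gene on the other strand. Those genes had 508698 and 600543 counts on their own strand, so the same reads were counted once for each gene of an overlapping pair. The percentages are therefore no share of antisense reads. At all other genes 26 and 39 reads lay on the opposite strand.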

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

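Of the tests given here, that of hairpin GC content was set before its result was seen, and the others were chosen afterwards. The design has 1 group, so no difference between groups of animals was tested as an explanation.

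Signal appeared in parts of the tables that the report does not assign to genes, above the 3 counts that a count of 0 allows. Reads matching several places numbered 7195252 in replicate 1 and 10919725 in replicate 2. Uniquely placed reads outside microRNA genes numbered 142257 and 232773. At the 2138 genes with no microRNA gene on the other strand, 26 and 39 reads lay on the opposite strand.

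Mir206, Mir499 and Mir208b were higher in replicate 2. Hairpin GC content as the whole cause is argued against by the lowest of their log2 ratios left after a linear fit on GC, 1.84. Heart muscle in the sample leaves the Mir206 ratio of 1.77 unaccounted for, since heart muscle does not make Mir206. For Mir499 and Mir208b, heart muscle as the cause was taken to bring at least as many reads of Mir208a as of Mir208b. That was not met in replicate 2, where Mir208a had 15 reads, 1.69 per 100 reads of Mir208b. Heart muscle stays open for these genes nonetheless, because Mir208a also rose, from 1 read in replicate 1. No heart library was at hand to say what ratio heart would bring. A different share of slow fibres in the dissected piece may be a candidate explanation, and it was not tested.

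Mir144 and Mir451a were lower in replicate 2. Mir451b, on the other strand of Mir451a, was named to look for lost Mir451a reads. It had 0 reads in both libraries, or 0% of the 51230 that Mir451a lacked in replicate 2 after scaling. Counts were taken by strand, so hardly any reads could be lost that way and the outcome was nearly fixed beforehand. Mir144, which has no microRNA gene on the other strand, was 4.25-fold lower as well. A candidate explanation is less RNA of whole blood in replicate 2, which stays open: of 4 leukocyte genes, 2 were higher (Mir150 and Mir155) and 2 lower (Mir142 and Mir223), and cells in the tissue also make these microRNAs. That all 4 must be higher to exclude blood was settled after these values were seen, and had any 1 been enough they would argue against it.

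Some genes with identical copies, such as Mir1a-1 (32 and 24 reads) and Mir133a-2 (8 and 12), both named after their values were seen, had few reads, whereas others, such as Mirlet7f-2 (7857 and 12534), had many. Uncounted reads could give higher counts to family members whose hairpin shares no 20-base stretch with another microRNA locus, but over 22 families the mean difference in log2(CPM + 1) was 0.43 ± 4.48 (SD), positive in 11, with a two-sided permutation p of 0.662. Of all genes that share such a stretch 6.07% were detected, against 18.6% of those that do not. The let-7 family (13.77 against 8.51) and the miR-26 family (14.16 against 3.78) had the higher mean in unique members, and the miR-378 family (5.40 against 11.69) and the miR-101 family (0.00 against 8.85) in sharing members. The test could not decide, since a shared stretch need not cost a gene its reads. Mir378a, the gene with the most reads, is itself a sharing member. The unique member of the miR-101 family and that of the miR-133 family had no reads. Lower transcription of duplicated genes cannot be told apart from uncounted reads, since the 4.88 reads matching several places per gene-assigned read are not divided by gene.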

How the results depend on the processing

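Among the alternatives for the main results, 25 values stayed within the limit set for them and 14 moved. The limit was the same call for a test, 1.5 times for a count, 10% for the coefficient of variation and the spread for a share or ratio. Within it, detected genes fell to 200 with at least 50 reads in both and 249 without regard to strand, and the chi-square per degree of freedom ran from 280 to 778. Without regard to strand, Mir378a fell from 15.9% to 0% of reads, because its reads overlap Gm25301, and the 10 most abundant genes held 62.4%. Mir126a fell from 10.04% to 0.00008% and Mir451a from 2.15% to 0%. The endothelial list fell to 0.0526%, the erythroid list to 0.247%, the glial list to 0% and the muscle differentiation list to 2.85%. Over gene-assigned and multiply matched reads together, chosen after the data were seen, the counted reads of Mir378a were 2.73%. None of the multiply matched reads could be credited to it. Requiring 1 read in both libraries gave 414 detected genes, as fewer reads were asked for. With edgeR's exact test at the common dispersion of these same 2 libraries, 4 genes passed in place of 172, 1 with at least 50 reads in both and 5 with no filter. With 188 genes the count for at least 10 reads in either library, also chosen afterwards, was close to the main one. The coefficient of variation was 0.40 with no filter and 0.302 with at least 50 reads in both. Without Mir378a and Gm25301, counts on the opposite strand were 14.7% of the counts on both strands, again with reads of overlapping genes counted for each gene.

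The erythroid median log2 ratio was -2.10 with total reads and -2.06 with at least 50 reads in both. The let-7 median was 0.33 with DESeq2 size factors, 0.28 with total reads and 0.33 with at least 50 reads, and the inflammation median was 0.96 with total reads. Another scaling moves every log2 ratio by the same amount, which was -0.067 for total reads. Requiring at least 50 reads in both also changes the scaling factors and can change which members are tested. Signs turned for the Dlk1-Dio3 median (-0.0026 with total reads), the endothelial median (0.18 with at least 50 reads, where Mir222 is no longer tested) and 5 genes. With total reads these were Mir322 (-0.012), Mir30e (-0.057), Mir10a (-0.044) and Mir27a (-0.014). With no filter they were Mir322 (-0.024), Mir30e (-0.069), Mir10a (-0.056), Mir27a (-0.026) and Mir133b (-0.0081). With at least 50 reads they were Mir30e (-0.015) and Mir10a (-0.0022), and with DESeq2 size factors Mir30e (-0.0052). Of these genes only Mir322 was called in the main test. Leaving out a replicate, which with 2 libraries cannot move a mean by more than their SD and is not among the values counted here, gave muscle microRNA shares of 2.21% to 6.98%, Mir378a shares of 14.4% to 17.4% and 282 to 293 detected genes. For single genes and lists 595 values kept their call or stayed within such a limit, 99 moved, 9 gained a call, 9 lost it and 14 turned. Depth limits genes under 10 reads, such as Mir208b in replicate 1.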

Other observations

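The test given here was chosen after pairs of the fixed clusters had been seen to differ alike, and those pairs are part of it.

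Genes within 10 kb of each other on the same strand may differ between the animals alike because they share a primary transcript. Over 61 such pairs, with each gene used once, the 2 log2 ratios had a Pearson's r of 0.42 (permutation p = 0.00123, adjusted p = 0.00615 over 5 relations) and a Spearman's rho of 0.31 (permutation p = 0.0169). Pairs had the same sign in 39 of 61 cases. The 2 pairs whose first gene by position lay farthest from the median were Mir144 with Mir451a and Mir181a-2 with Mir181b-2. The ratio of the second gene played no part in that choice. Without these 2 pairs r was 0.27 (permutation p = 0.0403, adjusted p = 0.0672), so its adjusted call rests on them. Spearman's rho moved little, to 0.27 (permutation p = 0.0365, not adjusted), and 37 of 59 pairs had the same sign. On chromosome 12, which holds the Dlk1-Dio3 cluster, 22 pairs had an r of 0.23 (permutation p = 0.30) and 10 had the same sign. On the other chromosomes 39 pairs had an r of 0.47 (permutation p = 0.00281, adjusted p = 0.00702). Without the same pairs, both of which lie there, 37 pairs had an r of 0.29 (permutation p = 0.0849, adjusted p = 0.106). Whether the 2 sets differ was not tested. These are correlations across genes of 2 libraries, and pairs are not independent replicates.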
